A study of Homo sapiens with 6 samples.

How the data were processed

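RNA from cultured PC3 cells, an established human prostate cancer cell line, was measured on 6 Illumina HumanRef-8 v3 BeadChip arrays with a single biotin label. The labels place 3 arrays in a group of cells expressing green fluorescent protein (GFP), which serves as the control, and 3 in a group of cells expressing the G protein-coupled receptor kinase GRK3. Per the labels' protocols, cells grew in RPMI medium with fetal bovine serum, RNA was purified on columns with a step that removes genomic DNA, and its quality was checked on a Bioanalyser.

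The table deposited by the authors gives an average bead intensity for each of 24526 probes on each array, on a linear scale and, per the file headers, not normalized. All of these values are above 0, and background had not been subtracted from them. The same deposited table gives a detection p-value per probe and array, which ranks the probe's signal among the negative control probes. The software and version that made these columns are not given in the sources used here. A second deposited table, the authors' value table, also holds intensity on a linear scale. Each of its columns equals the first table's column times 1 factor per array, between 0.931 and 1.10, and all of its columns have a mean of 1291.94. Its column medians lie between 131.6 and 140.7. Its scale, lack of centring and direction were settled by this comparison, and it was used only as an alternative.

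Probes were named from the platform's probe annotation, with symbols brought to current ones through the Entrez gene identifier. Of the probes, 21834 have 1 gene symbol, 2692 have none and 0 have several. The identifier was found in the reference gene table for 21813 probes, and 0 symbols had to be updated.

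Mean signal per array lay between 1171 and 1387, and between 13780 and 14363 probes per array (56.2% to 58.6%) were detected at a detection p-value under 0.05. The number of arrays limits the precision. The labels do not say whether the 3 arrays of a group came from separate cultures, so the p-values of probes measure only the spread between these samples, which may be technical.

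Values were background-corrected, quantile-normalized and put on a log2 scale with neqc of limma 3.58.1 in R 4.3.3, using the detection p-values to estimate background and an offset of 16. Probes detected on at least 3 of the 6 arrays were tested, 14130 in all, covering 10586 named genes. The remaining 10396 were not tested. GRK3 arrays were compared with GFP arrays by lmFit and eBayes of limma, a two-sided moderated test, with no covariate. Adjusted p-values are limma's with the Benjamini-Hochberg adjustment over the probes tested, and a probe passed at an adjusted p under 0.05. Differences are GRK3 minus GFP on the log2 scale, given with their standard error (SE). Group levels are means ± SD with n = 3. A probe detected on 0 arrays of a group is given as at least N-fold, from the other group's mean against the mean of, per array, the higher of the lowest detected signal and the probe's own.

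Gene groups were 34 lists, of which the 33 with at least 5 tested genes were tested with camera of limma (preset inter-gene correlation 0.01) and Benjamini-Hochberg adjustment over the lists. Camera compares the genes of a list with the other genes, so its p does not rest on the spread between arrays alone. The same test with an estimated correlation, and fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, were run beside it. A gene with several tested probes was represented by the probe with the highest mean over the 6 arrays.

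The groups, the test, the lists, the alternatives and the rule for naming genes were fixed before the data were examined, apart from 2 covariates named as later additions. The rule takes the 15 largest increases and the 15 largest decreases among named probes that passed with no overlap between the groups, up to 4 members past the threshold from any list that passed or had at least 3 such members, up to 3 from other lists that are described, and a fixed set. That set is THBS1, SERPINB2, VEGFA, PLAU, PLAUR, CHGA, ENO2, CDH1, VIM, MKI67, GRK2, GRK5, GRK6, ARRB1, ARRB2 and CXCR4, besides GRK3 itself. SERPINB2 and ARRB2 had no probe named here, and CHGA, GRK2 and CXCR4 did not pass the detection filter. List members named for passing over their list alone, and genes with several probes, were chosen after their values were seen.

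The alternatives were no background correction, an offset of 50, median scaling, the authors' value table, 3 other detection filters, an intensity trend, array weights, the replicate number as a block, each array left out in turn, the mean of a gene's probes, and the other list tests. The tests were tried on 20 simulated data sets of 14130 probes, with 200 probes changed in each. They recovered 39.2% of the probes changed by 0.5 on the log2 scale and 89.2% of those changed by 1, and 4.06% of the calls were false. With no probe changed, a mean of 0.05 probes passed. The simulated noise was independent between probes and arrays, without the shared axis among the real arrays described below. These rates therefore need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.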

Results

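The series asks which genes GRK3 regulates in PC3 cells. GRK3 (older symbol ADRBK2) is a kinase that phosphorylates activated G protein-coupled receptors. Expression was measured on 3 arrays of PC3 cells carrying GRK3 and 3 arrays of PC3 cells carrying GFP, and 14130 probes were compared. Whether each group is a pool or a clone of cells is not given in the sources used here, so the differences are between these cell populations and cannot be assigned to GRK3 alone.

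In the GRK3 cells the cytokine genes IL1B and IL6 were lower, and MSMP and MMP10 were higher. IL1B and IL6, which encode the cytokines interleukin-1 beta and interleukin-6, fell by 1.45 ± 0.14 (SE) and by 1.13 ± 0.09 (SE) on the log2 scale (limma adjusted p = 0.00179 and 0.000825). The largest increase was in MSMP, which encodes a small secreted microseminoprotein, at 2.39 ± 0.28 (SE), a 5.24-fold difference (limma adjusted p = 0.00531). MSMP was also among the genes furthest out on the replicate axis described below. The largest decrease was in PODNL1, a gene of the small leucine-rich proteoglycan family, which fell by 2.31 ± 0.11 (SE), a 4.97-fold difference (limma adjusted p = 3.76e-05). MMP10, the matrix metalloproteinase stromelysin-2, was higher by 1.79 ± 0.18 (SE), with a limma adjusted p of 0.00279.

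Across all probes tested with limma, 81 passed, 53 of them higher and 28 lower in GRK3 cells. Fitted differences of at least 2-fold made up 20 of the increases and 11 of the decreases. One unnamed probe among these decreases was detected on 0 GRK3 arrays, so its decrease is only known to be at least 1.65-fold. The 3 GRK3 arrays lay on 1 side of the 3 GFP arrays for all 81 probes. With 3 arrays per group a call all but requires this, so it adds no support. Over all tested probes such separation held for 16.4%, against 10% by chance. Without adjustment, 1636 probes had a p under 0.05, where chance gives 706.5. Of the 81 probes, 73 are named and 8 are not (3 higher and 5 lower), and 13 shared the highest adjusted p among them, 0.0497. The median within-group SD was 0.13 and the median difference over all probes was -0.01, both on the log2 scale. Leaving out 1 array changed the count of 81 to 39 without GFP replicate 1, 24 without GFP replicate 2, 30 without GFP replicate 3, 183 without GRK3 replicate 1, 23 without GRK3 replicate 2 and 35 without GRK3 replicate 3. All 81 kept their sign in each of these runs, which the separation of their groups made all but certain beforehand.

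The transgene's own gene could not be read from the arrays. The single GRK3 probe was not above background on any of the 6 arrays, with detection p-values from 0.104 to 0.262. Its normalized log2 values were 5.43, 5.34 and 5.31 on the GFP arrays and 5.46, 5.40 and 5.23 on the GRK3 arrays, so no fold is given. Where this probe lies relative to the sequence carried by the transgene is not given in the sources used here, so the probe does not check the labels.

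The 15 named genes with the largest increases had limma adjusted p-values from 0.000947 to 0.0497. HPGD, the dehydrogenase that inactivates prostaglandins, rose from 7.73 ± 0.26 to 9.68 ± 0.49 (SD, n = 3 each), a difference of 1.95 on the log2 scale. TBXAS1, which encodes thromboxane synthase, rose by 1.08. CLDN10, a claudin of tight junctions, rose by 1.52, though only 2 of the 3 GFP arrays detected it. PRR4, MUCL1 and ZG16B, which encode secreted proteins, rose by 1.44, 1.12 and 1.10. CLCA2, a chloride channel accessory gene, rose by 1.24 and FLVCR2, a membrane transporter, by the same 1.24. VSIG1, an adhesion gene of the immunoglobulin superfamily, rose by 1.34. RASL11A and PLAAT4 each rose by 1.16. IGFBP5 was higher (limma adjusted p = 0.0113), by an amount left out here because only 1 of the 3 GFP arrays detected it. COL5A2, a chain of collagen V, rose by 1.10.

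The 15 named genes with the largest decreases had limma adjusted p-values from 3.76e-05 to 0.0497. PI3, which encodes the elastase inhibitor elafin, fell from 13.52 ± 0.05 to 12.32 ± 0.12 (SD, n = 3 each). IL13RA2, a receptor for interleukin-13, fell by 1.15, and IL18R1, a subunit of the interleukin-18 receptor, fell by 0.80. DAW1 was lower (limma adjusted p = 0.0107), by an amount left out here because only 1 of the 3 GRK3 arrays detected it. CYTH4, KLHL26 and the carboxypeptidase gene CPA4 fell by 0.70, by 0.70 and by 0.69. THBS1, which encodes thrombospondin-1, an inhibitor of angiogenesis, fell from 12.66 ± 0.23 to 11.76 ± 0.30 (SD, n = 3 each). The limma adjusted p of THBS1 was 0.0497, and its call ended when any array but GRK3 replicate 1 was left out, at 0.0626 without GFP replicate 1, 0.234 without GFP replicate 2, 0.162 without GFP replicate 3, 0.175 without GRK3 replicate 2 and 0.163 without GRK3 replicate 3. Over all alternatives the adjusted p of THBS1 ran from 0.000935 to 0.25.

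**Figure D1:**
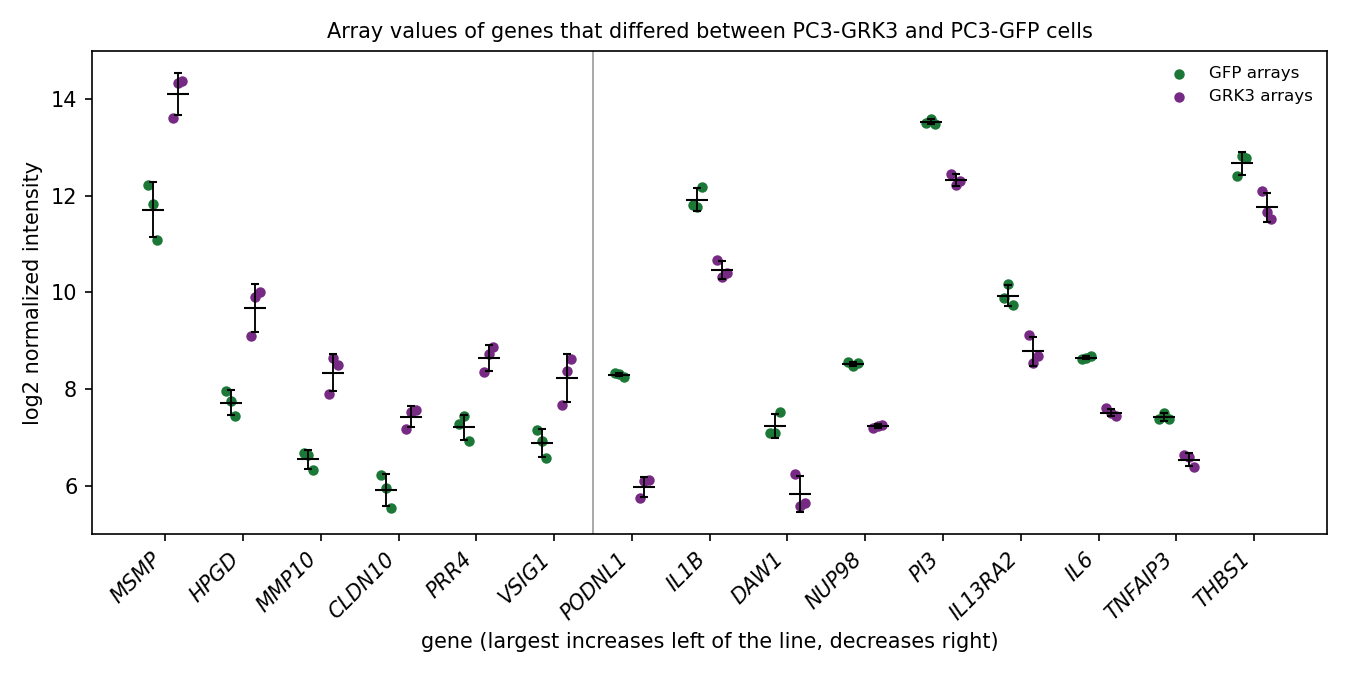
Normalized log2 intensity (y axis) of 15 genes (x axis) on the 3 GFP arrays and the 3 GRK3 arrays, 1 point per array, with the group mean as a horizontal bar and the SD as the error bar. For each gene the groups do not overlap, as the rule that chose these genes required. MSMP averaged 11.71 in GFP and 14.10 in GRK3 cells, and PODNL1 8.30 and 5.99.

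Of the 30 genes named by size, 15 passed with each array left out in turn: MSMP, HPGD, MMP10, CLDN10, PRR4, CLCA2, FLVCR2, PLAAT4, MUCL1, PODNL1, IL1B, NUP98, PI3, IL6 and TNFAIP3. Of the 30 genes, 9 no longer passed without GFP replicate 1, 14 without GFP replicate 2, 12 without GFP replicate 3, 0 without GRK3 replicate 1, 15 without GRK3 replicate 2 and 11 without GRK3 replicate 3.

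Probes of 1 gene differed in size and in whether they passed. NUP98, which encodes a nuclear pore protein, fell by 1.29 at 1 probe (limma adjusted p = 0.000282), while its other probes differed by -0.28 and -0.24 (limma adjusted p = 0.255 and 0.424). The interferon-induced gene IFIT3 rose by 0.69 at its dimmest probe and had differences of 0.29 and 0.49 at brighter ones, with limma adjusted p-values of 0.02, 0.382 and 0.0761. COL6A2, a chain of collagen VI, fell by 0.63 at 1 probe, and differed by -0.50 at its brightest and -0.01 at its dimmest (limma adjusted p = 0.0434, 0.0645 and 0.992). CTSH, which encodes cathepsin H, rose by 0.72 at its brighter probe and differed by 0.03 at the other (limma adjusted p = 0.0404 and 0.963). At the brighter probe CTSH did not pass without GFP replicate 2 (0.187), GFP replicate 3 (0.152), GRK3 replicate 2 (0.164) or GRK3 replicate 3 (0.149), in a range from 0.00482 to 0.233 over all alternatives.

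Among the fixed lists, the group of NF-kB cytokines and targets fell (camera adjusted p = 8.56e-08, median difference -0.27), with an adjusted p = 0.0953 with an estimated correlation, the highest over the alternatives, whose lowest was 1.05e-08. The correlation estimated for this list was -0.009, below the preset 0.01. A higher correlation among its members therefore does not account for the loss of the call. Of its 20 tested genes, 4 fell, 0 rose and 16 did not pass. The 4 were IL1B, IL6, TNFAIP3, which encodes the NF-kB feedback inhibitor A20 and fell by 0.88, and IL1A, which fell by 0.73. Adjusted over the list alone, 7 were lower, adding IL11, CXCL2 and IL32, and 1, the chemokine gene CCL5, was higher. Among the runs with 1 array left out, IL11 passed over all probes only without GRK3 replicate 1 (limma adjusted p = 0.00692). In the other such runs its limma adjusted p was from 0.222 to 0.283. Fry gave an adjusted p of 0.00172. In the splits of the arrays that mixed the groups, described below, this list had camera adjusted p-values of 0.0751 or higher. The lowest camera adjusted p of any list in those splits was 2.80e-06, for the unfolded protein and amino acid stress response. A very small camera p can therefore arise without a difference between the groups. IL1A did not pass without GFP replicate 2 (limma adjusted p = 0.14), GFP replicate 3 (0.09), GRK3 replicate 2 (0.142) or GRK3 replicate 3 (0.0721), with a range of 0.00482 to 0.142 over its alternatives.

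The type I interferon response list was higher (camera adjusted p = 0.0213, median difference 0.09), although 0 of its 26 tested genes passed over all probes tested with limma at the probe used for the list. It did not pass with an estimated correlation (adjusted p = 0.671 with an estimated correlation) or with fry (0.293). The correlation estimated for this list was 0.086, above the preset value. This list also passed camera in a split of the arrays that mixed the groups, described below. The split of GFP replicates 1 and 2 with GRK3 replicate 1 against the rest gave a camera adjusted p of 0.00219. That is lower than for the real groups, so the camera call of this list does not set the real grouping apart. Adjusted over the list alone, 7 were higher: IFIT1, BST2, IFIT2, OAS2, OASL, HERC5 and ISG15, with differences between 0.35 and 0.59. The camera adjusted p was 0.201 without GFP replicate 2 and 0.0675 without GRK3 replicate 3, where the median was 0.00 against 0.21 without GRK3 replicate 1, and it ran from 0.00198 to 0.671 over the alternatives.

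The list of mesenchymal markers did not pass (camera adjusted p = 0.0606, and 0.671 with an estimated correlation, in a range from 0.0134 to 0.671 over the alternatives). It passed in 11 of 21 alternatives, among them the run without GRK3 replicate 1 (0.0185), and its median of -0.10 was -0.06 without GFP replicate 2. Of its 12 tested genes, CDH2, which encodes N-cadherin, fell by 0.65 (limma adjusted p = 0.0381) and 11 did not pass. CDH2 passed only with GRK3 replicate 1 left out among the 6 such runs, and had adjusted p-values of 0.119, 0.14 and 0.143 without GFP replicates 1, 2 and 3, and of 0.14 and 0.104 without GRK3 replicates 2 and 3 (range over all alternatives 0.00412 to 0.143). Vimentin (VIM) had a difference of -0.66 and a limma adjusted p of 0.0645, and adjusted over the list alone both CDH2 and VIM were lower. VIM passed in 9 of 18 alternatives (range 0.00389 to 0.259), among them the run without GRK3 replicate 1 (0.0378). SNAI2 differed by -0.83 ± 0.30 (SE), with a limma adjusted p of 0.32. Among the runs with 1 array left out it passed only without GRK3 replicate 1 (0.0414, in a range from 0.000501 to 0.652 over all alternatives). These counts and ranges include the 2 covariate runs added later. The mesenchymal list lay far out on the replicate axis described below, with 0.23% of matched random lists as low. SNAI2 was among the genes furthest out on that axis. E-cadherin (CDH1) differed by 0.02, with a 95% interval from -0.23 to 0.27.

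The YAP/TEAD target list did not pass either (camera adjusted p = 0.0752, and 0.671 with an estimated correlation, in a range from 0.0187 to 0.671), with a median of -0.18 over 18 tested genes. It passed in 7 of 21 alternatives, among them the run without GRK3 replicate 2 (0.0187), and the median was -0.11 without GRK3 replicate 3. Its 1 member past the threshold went the other way: CCN2, which encodes connective tissue growth factor, rose by 0.82 ± 0.11 (SE), with a limma adjusted p of 0.0102. CCN2 had adjusted p-values of 0.0565 without GFP replicate 1, 0.0508 without GFP replicate 3 and 0.0603 without GRK3 replicate 2 (range over all alternatives 0.0013 to 0.0654). Adjusted over the list alone, GADD45A was also lower, with a difference of -0.46, and it passed over all probes in 8 of 18 alternatives. CCN2 was also the 1 gene of 19 to pass in the list of TGF-beta and SMAD targets (camera adjusted p = 0.836), where 1 was higher and 1 lower adjusted over the list alone.

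**Figure D2:**
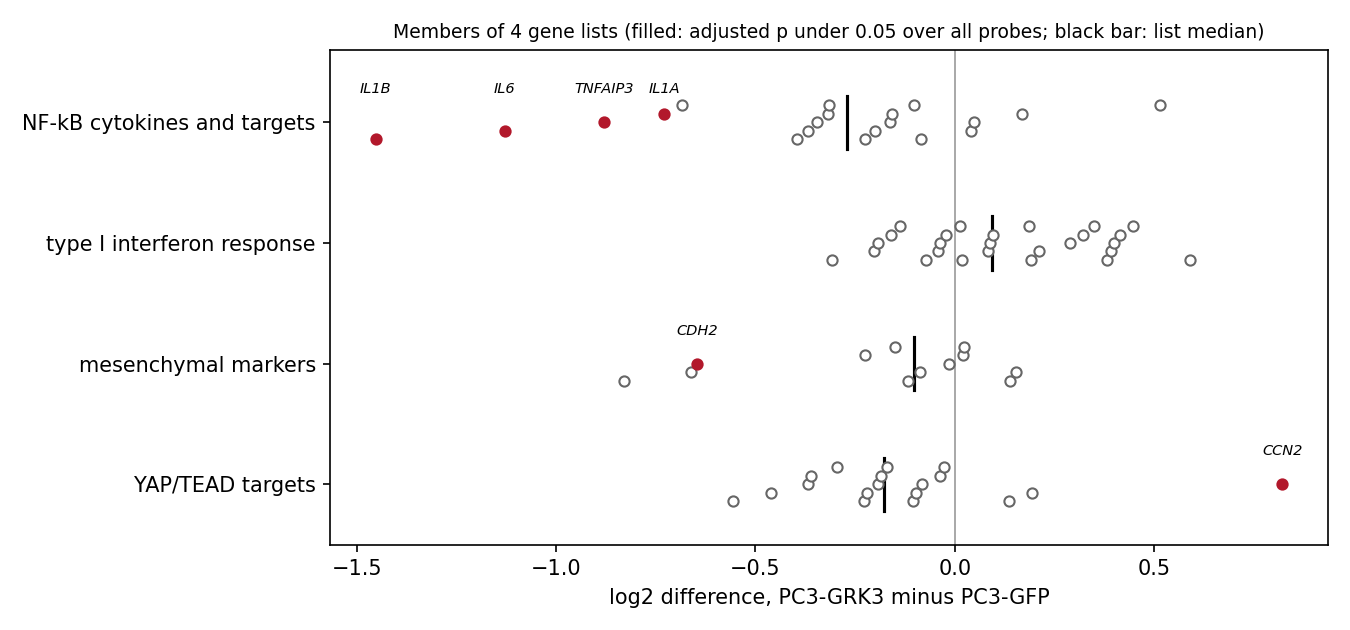
Log2 difference between GRK3 and GFP cells (x axis) of each tested member of 4 gene lists (y axis), 1 point per gene, filled where the limma adjusted p over all probes was under 0.05, with the list median as a black bar. The medians are -0.27 for NF-kB cytokines and targets, 0.09 for the interferon response, -0.10 for mesenchymal markers and -0.18 for YAP/TEAD targets.

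Genes of the extracellular matrix moved in both directions. In this list of 25 tested genes, COL5A2 rose, COL5A1 fell by 0.56 (limma adjusted p = 0.0497) and 23 did not pass at the probe used for the list (camera adjusted p = 0.593). Adjusted over the list alone, 4 were lower, COL5A1, COL6A1, COL6A2 and LAMB3, and 1, COL5A2, was higher. Among the runs with 1 array left out, LAMB3 passed over all probes only without GRK3 replicate 1 (limma adjusted p = 0.0431), and was from 0.25 to 0.408 in the others. The call of COL5A1 ended with each array left out, at adjusted p-values from 0.0506 without GRK3 replicate 1 to 0.198 without GRK3 replicate 3 (range over all alternatives 0.016 to 0.233). COL5A2 passed only without GRK3 replicate 1 among those runs, with an adjusted p of up to 0.0888 without GFP replicate 2 (range over all alternatives 0.000669 to 0.0888). Of 14 tested metalloproteinases and inhibitors, MMP10 rose, also the 1 call adjusted over the list alone, and 13 did not pass (camera adjusted p = 0.749).

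Of 10 tested angiogenesis inhibitors, THBS1 fell, also the 1 call adjusted over the list alone, and 9 did not pass. The median of this list was 0.06 while its mean, -0.03, and the direction of its test (camera adjusted p = 0.984) were negative. Without GRK3 replicate 1 the median was 0.11, without GRK3 replicate 3 it was 0.01, and without GFP replicate 1 it was 0.09. None of 19 angiogenic factors passed over all probes with limma (camera adjusted p = 0.593), and adjusted over the list alone 2 were higher, ANG and PDGFB, and 3 lower, HBEGF, CXCL2 and CXCL6. HBEGF passed over all probes only without GRK3 replicate 1 (limma adjusted p = 0.0319) among the runs with 1 array left out. In the other such runs its limma adjusted p was from 0.136 to 0.388. VEGFA differed by -0.05, with a 95% interval from -0.39 to 0.30. PLAU, the urokinase gene, differed by -0.04 (95% interval from -0.38 to 0.30) and its receptor gene PLAUR had a 95% interval from -0.55 to 0.06 (limma adjusted p = 0.542).

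Of 9 tested neuroendocrine markers, 1 passed: CPE, which encodes the prohormone-processing carboxypeptidase E, rose by 0.57 ± 0.10 (SE), with a limma adjusted p of 0.0404 and a camera adjusted p of 0.477 for the list. Adjusted over the list alone it was again the 1 call. SCG5, the member with the largest difference, went the other way at -0.88 ± 0.54 (SE), with a limma adjusted p of 0.598. It was the gene furthest out on the replicate axis described below. This list also lay far out there, with 0.82% of matched random lists as low. CPE passed only without GRK3 replicate 1 among the runs with 1 array left out. It had an adjusted p of 0.187 without GFP replicate 2 (range over all alternatives 0.0127 to 0.187), and did not pass with the authors' value table. ENO2 had a 95% interval from -0.35 to 0.19 (limma adjusted p = 0.867). The proliferation marker MKI67 had a 95% interval from -0.08 to 0.58 (limma adjusted p = 0.568).

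None of 26 tested GPCR kinases, arrestins and RGS genes passed with limma (camera adjusted p = 0.477). GRK5, GRK6 and ARRB1 had 95% intervals from -0.47 to 0.02, from -0.17 to 0.42 and from -0.19 to 0.36. RGS4, a regulator that speeds GTP hydrolysis by G proteins, differed by -0.96 ± 0.19 (SE), with a limma adjusted p of 0.0645, and was lower adjusted over the list alone. RGS4 passed over all probes in 10 of 18 alternatives (range 0.000318 to 0.259), among them the run without GRK3 replicate 1 (0.00631). In the list of cAMP and CREB targets 0 of 17 passed with limma (camera adjusted p = 0.593), and PDE4B and ATF3, with differences of -0.47 and -0.74, were lower adjusted over the list alone. The remaining lists, with the mesenchymal and YAP/TEAD lists among them, had camera adjusted p-values from 0.0606 to 0.984. Among them, the heat shock protein list passed in 2 of 21 alternatives, 1 of them without GFP replicate 3 (0.0103), and the oxidative phosphorylation list in 3 of 21, with a lowest adjusted p of 0.00208. The list of basal and stem markers was lower with fry (adjusted p = 0.00426) but did not pass camera (adjusted p = 0.276). Of its 12 tested genes 0 passed over all probes with limma, and EGFR, at -0.42, was lower adjusted over the list alone.

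None of the 5 tested leukocyte markers of the fixed list passed with limma (camera adjusted p = 0.64), with differences of 0.18 for CD68, 0.15 for LYZ and -0.09 for CD14. None of the 4 tested fibroblast and endothelial markers of the fixed list passed with limma, with differences of 0.29 for LUM, 0.25 for PDGFRA and 0.21 for PECAM1.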

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

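The covariate runs were chosen after the data were seen; the other alternatives were planned. All 81 probes kept their sign in every alternative that tested them. For the runs with an array left out this follows from the separation of their groups. Counts of calls moved, and the cause was not tested, also where fewer arrays or more probes entered. Higher and lower probes numbered 91 and 48 without background correction (2-fold 10 and 6), 78 and 44 with an offset of 50 (2-fold higher 13), 57 and 55 with the authors' value table (50.9% higher, against 65.4%; 2-fold 11 and 7), and 14 and 9 with no detection filter, which tests 24526 probes (2-fold 5 and 7). They numbered 89 and 47 with an intensity trend and 161 and 78 with array weights (2-fold higher 37). With detection on all 6 arrays at 0.01, 2-fold calls numbered 8 and 7. With each array left out, higher calls ranged from 14 to 128, lower from 9 to 55, 2-fold higher from 10 to 45 and 2-fold lower from 8 to 17. With the first within-group component as a covariate they were 269 and 147 (2-fold higher 31), and with the hypoxia list mean 190 and 110. Lists called numbered 6 with median scaling, 5 with the authors' value table, 4 with no filter, 4 with detection on all 3 arrays of a group, 4 with the mean of a gene's probes, 4 and 5 with the covariates, 0 with an estimated correlation, and from 1 to 3 with arrays left out. Fry called 2, the NF-kB list and the basal and stem marker list. The replicate number as a block left 4 higher and 7 lower probes, all at least 2-fold. Deviations of arrays with the same number correlated at -0.407, 0.178 and -0.415. The replicate axis described below holds 48.3% of the within-group variance, and the numbers do not pair the arrays along it. A smaller effect shared by arrays of the same number is not excluded. Differences near 0 changed sign: PLAU was 0.0405 with median scaling and 0.0159 with the hypoxia covariate, VEGFA 0.0443 with array weights, CDH1 -0.0102 with the hypoxia covariate, CD68 -0.23 with the mean of its probes and the median of the G1/S cell cycle list 0.00397 with median scaling. With arrays left out, VEGFA ranged from -0.14 to 0.13, PLAU from -0.17 to 0.12 and CDH1 from -0.0828 to 0.12. PLAUR ranged from -0.41 to -0.15, ENO2 from -0.18 to -0.01, MKI67 from 0.13 to 0.39, GRK5 from -0.28 to -0.13, GRK6 from 0.02 to 0.22 and ARRB1 from 0.00 to 0.20. Of the 30 genes named by size, 8 passed in every alternative that tested them. The GRK3 probe was detected on 0 arrays in the 9 runs that changed arrays or filters, as its detection p-values fix beforehand. A slide block was not run, since no slide is given in the sources used here. Signal over background limits calls near the floor: 10396 probes were not tested.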

Other observations

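Tests of the replicate axis, of the GRK3 probe, and of the NF-kB list with the hypoxia covariate were chosen after those results were seen, as were the genes of the next paragraph; the tests of other splits and of matched random lists for the NF-kB list were written beforehand.

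Among further genes past the threshold, S100A8, a calcium-binding protein, rose by 0.83 ± 0.10 (SE, limma adjusted p = 0.00517). FGB, the fibrinogen beta chain, was detected on 0 of the 3 GFP arrays and all 3 GRK3 arrays, and was higher by at least 1.64-fold (limma adjusted p = 0.00254). Both passed with each array left out in turn. None of 20 targets of NRF2, the oxidative stress regulator, passed over all probes with limma (camera adjusted p = 0.276). Adjusted over that list alone 3 were higher, AKR1C2, AKR1C3 and GPX2, the first pair at 0.44 and 0.45.

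The lower NF-kB list was set against array effects. Of 10000 random lists matched on mean signal, 0% had a median as low as -0.27, which argues against a bias that depends on signal. With the hypoxia list mean as a covariate the median was -0.25 (-0.2496 to 4 decimals). That mean differed by only 0.04 between the groups, so the covariate could hardly move the median. The run by itself therefore decides little about the position of the arrays on the hypoxia axis. The NF-kB list did not lie far out on the replicate axis described below, with 26.1% of matched random lists as low. This and the small difference in the hypoxia mean argue against array position on that axis as the source of the lower list. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split was 1 of 10 with a median difference this large, at 0.27 in size, and the highest other was 0.15. Only transcripts were measured, so whether NF-kB activity was lower stays open, and a difference in cell history or array processing was not tested.

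The same 10 splits bear on the counts. As many probes as the real 81 passed in 1 split, the real one, and the highest other count was 0; for calls with a fitted difference of at least 2-fold these were 31, with the 1 probe bounded at 1.65-fold among them, and 0. For lists, 5 splits gave at least the real 2, and the highest other gave 5, so the count of lists passing camera does not set the real grouping apart. The splits are too few for a share under 0.05. The split of GFP replicate 1 with GRK3 replicates 2 and 3 against the rest gave 2089 probes at an unadjusted p under 0.05, more than the real 1636, which points to a structure among the arrays other than the groups.

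That structure was an axis along which replicates spread in both groups. The first component of the deviations from the group means held 48.3% of the within-group variance, with scores of 0.43, 0.01 and -0.44 for GFP replicates 1 to 3 and -0.63, 0.18 and 0.45 for GRK3 replicates 1 to 3. GRK3 replicate 1 lay furthest out, and the run without it gave 183 calls. The hypoxia list mean spread by 0.28 within GFP and 0.27 within GRK3 arrays, against 0.04 between the groups, and NDRG1 ranged from 11.69 to 12.41 in GFP and from 11.44 to 12.43 in GRK3 cells. MSMP also followed the axis, at 12.22, 11.82 and 11.09 on GFP replicates 1 to 3. On GRK3 replicates 1 to 3 it was at 13.60, 14.32 and 14.37. Over all tested probes, position on the axis and the group difference correlated at 0.247. Pooled hypoxia, glycolysis, stress response and heat shock genes spread more than matched random lists in both groups (0% of 10000 spread as much). The lists were picked because they lay out on this axis, so the test leaves a signal-dependent bias open. The state of each culture at harvest is a candidate explanation: 4 of these 4 lists lay at the same end of the axis beyond 95% of matched random lists, but epithelial and GPCR lists lay there too, so culture state, RNA handling and array bias cannot be told apart.

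The GRK3 probe was at background in cells labelled as carrying GRK3. The first explanation tested is that the probe lies outside the part of the transcript that the transgene carries, and the probe was detected on 0 GRK3 arrays. The second is that labels of GFP and GRK3 arrays were exchanged, and the probe was detected on 0 GFP arrays. The first count restates the observation. An exchange of labels by itself would not account for background on the arrays of both groups. Neither count decides where the probe lies or whether labels were exchanged, and the probe and transgene sequences are needed. Whether the GRK3 transcript was raised in the GRK3 cells is not shown either.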
